A study of Homo sapiens with 6 samples.

How the data were processed

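Sequencing libraries of mRNA were made from HEK-293T cells, a transformed human embryonic kidney line, per the labels' protocols. The cells had been kept for 12 h in medium with DMSO, the solvent, or with 10 µM nitidine chloride, a benzophenanthridine alkaloid. Each condition had 3 libraries. Groups and replicate numbers were taken from the sample labels.

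The deposited table held raw read counts per gene, per the file headers and the values, which were whole numbers with a different total in each library. It also held FPKM per the file headers, a value scaled by the authors to gene length and to the total of counted reads. For values with at least 50 counts, the gene length recovered from count and FPKM lay within 1% of the gene's median length in 100% of cases, so both kinds of columns describe the same counting. HISAT2 2.0.4 and StringTie 1.3.0 are named in the submitters' processing notes, with no roles. The read counter, its strand setting, the genome build and the annotation are not given in the sources used here. Gene positions in the table were identical to those of GENCODE release 29, on the human assembly GRCh38, for 47538 of the 50111 gene identifiers present in both. Positions are given here as the table gives them. Genomic span is the distance from start to end of a gene in the table, introns included. FPKM length is the length behind the authors' FPKM. For ATF4 it is 4119 bp against a span of 2991 bp, so it is not a mature transcript length.

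The table listed 50868 genes, of which 22254 had no counts in any library. Library totals ran from 12688093 to 16357992 counts. Genes with a mean of at least 10 counts over the 6 libraries were tested, which left 15953. Normalisation used the TMM method, and the main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of nitidine chloride against DMSO with no other covariate, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are given as CPM (counts scaled to the library total) after TMM scaling, computed here from the deposited counts, as mean ± SD over 3 libraries. The standard error (SE) of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic.

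The test, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The lists held 995 entries, all of which were matched to a gene of the table. They covered stress pathways, mTORC1 and insulin signalling, autophagy and lysosomes, lipid synthesis, the cell cycle, ribosomes, mitochondria, inflammation, cell death and markers of 4 other cell types. Each list was tested with camera (limma 3.58.1), a comparison with all other tested genes, at a preset correlation of 0.01 between genes and with adjustment over the lists. Counts of list members past the threshold are given with adjustment over all genes and adjusted over the list alone. Named genes were ATF4, SESN2, IGF2R and MTOR from the study's stated topic, the 8 genes with the highest and the 8 with the lowest fold change among those past the threshold with separated groups and a mean FPKM of at least 5 in the higher group, and up to 2 members per list and direction with the most extreme fold changes. Some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

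The alternatives were a replicate block, each library left out in turn, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0 with its size factors, scaling by library size alone, limma-voom, an adjusted p threshold of 0.01, a test against a 1.5-fold change, camera with an estimated correlation, and fry. List tests on values adjusted for genomic span, with the preset and with an estimated correlation, and a count without genes overlapped by another counted gene were added after the data had been seen. The span-adjusted tests, also those of gene families, used signed z-scores from edgeR's p-values, less their trend with span. Camera in the main test used the counts, so a difference between both results need not come from span. Alternatives that applied only to a table without counts, such as another pseudocount or quantile normalisation, were not run. Overlaps between genes were found with GenomicRanges 1.54.1, transcript GC content came from GENCODE release 29 for 15870 of the tested genes, and plots were drawn with matplotlib 3.10.9.

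The count test was tested on simulated data for this comparison, with 15817 genes drawn from the real means and library sizes. It called 33.3% of 66 genes changed 1.5-fold, 70.5% of 61 changed 2-fold and 96.8% of 62 changed 4-fold. Of 133 calls, 8 were false. Few genes were changed in the simulation, against 51.7% of tested genes in the real data. Its adjusted threshold was thus stricter, so the shares called do not measure the sensitivity of this comparison. The list test recovered the shifted list and called 0 of the other lists, but the simulated genes were drawn independently. The real lists had estimated correlations between genes of up to 0.402, so lists whose genes vary together were not covered.

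Libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom of 8.53 to 15.8, so no pair was treated as copies of one library. Correlations of log2 CPM between libraries were 0.982 to 0.987 within groups and 0.926 to 0.932 between groups. The labels do not say that the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Because the strand setting is not given, genes that overlap others, and near-identical copies, have uncertain counts. EEF1A1P5, a processed pseudogene, had 6645 CPM in DMSO against 1690 CPM for its parent EEF1A1, and RPS2P5 had 2721 CPM against 984.9 CPM for RPS2. Reads of abundant genes may therefore in part have been counted on such copies, which was not tested.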

Results

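RNA of HEK-293T cells treated for 12 h with DMSO or with 10 µM nitidine chloride was measured by mRNA sequencing, with 3 libraries per group. The DMSO libraries held 12688093, 14563014 and 16357992 counts and the nitidine chloride libraries 13685873, 15620937 and 13273432. The share of counts on mitochondrially encoded genes was 3.80% to 3.94% in the DMSO libraries and 3.39% to 3.46% in the nitidine chloride libraries. The 10 most abundant genes of each library took 5.85% to 6.19% and 4.99% to 5.13% of its counts, in the same order. The comparison addresses which transcripts change when the alkaloid is present, with mTORC1 signalling, the transcription factor ATF4, Sestrin2 and the receptor IGF2R as the study's stated subjects.

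SESN2, which encodes the stress-induced mTORC1 inhibitor Sestrin2, rose from 99.2 ± 2.31 to 283.0 ± 14.1 CPM (mean ± SD, n = 3), a log2 fold change of 1.51 ± 0.06 (SE). ATF4, the main transcription factor of the integrated stress response, rose from 785.6 ± 16.0 to 1025 ± 41.0 CPM, a log2 fold change of 0.38 ± 0.05. IGF2R, the cation-independent mannose 6-phosphate receptor that also binds IGF2, fell from 305.8 ± 14.9 to 132.1 ± 6.47 CPM, a log2 fold change of -1.21 ± 0.07. MTOR, the kinase of the mTOR complexes, fell from 252.2 ± 7.16 to 107.6 ± 4.97 CPM, a log2 fold change of -1.23 ± 0.06. All 4 genes had separated groups. The adjusted p-values of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1.51e-06 for SESN2, 7.15e-04 for ATF4, 5.38e-06 for IGF2R and 3.53e-06 for MTOR.

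SESN2 (ENSG00000130766) lies on chromosome 1 from 28259527 to 28282491, and ATF4 (ENSG00000128272) on chromosome 22 from 39519695 to 39522685. IGF2R (ENSG00000197081) lies on chromosome 6 from 159969099 to 160113507 and spans 144.4 kb, with the transcript AL353625.1 annotated inside it on the same strand. MTOR (ENSG00000198793) lies on chromosome 1 from 11106535 to 11262507 and spans 156.0 kb. Tested genes with a span within a factor of 0.8 of that of IGF2R in either direction, 1124 in number, had a median log2 fold change of -0.91, and 26.1% of them were lower than IGF2R. For MTOR there were 1008 such genes with a median of -1.0, and 32.3% were lower than MTOR. For ATF4 there were 678 with a median of 0.18, of which 65.2% were lower than ATF4, and for SESN2 1775 with a median of 0.23, of which 98.7% were lower than SESN2.

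**Figure D1:**
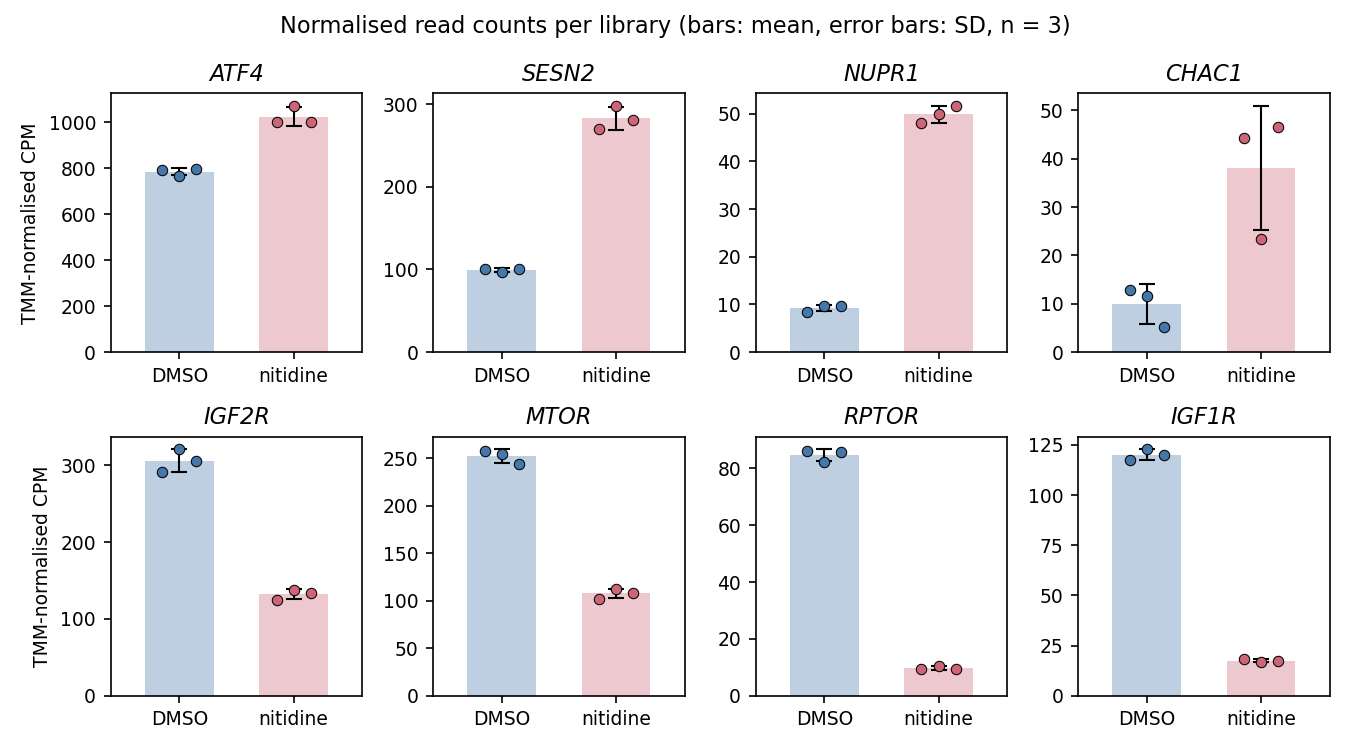
TMM-normalised CPM of 8 genes in each library, with DMSO and nitidine chloride on the horizontal axis, bars for the mean of 3 libraries, error bars for the SD and points for single libraries. SESN2 went from a mean of 99.2 to 283.0 CPM, whereas IGF2R went from 305.8 to 132.1 CPM and MTOR from 252.2 to 107.6 CPM.

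Across the transcriptome, 8250 of 15953 tested genes changed (51.7%), 3936 higher and 4314 lower after nitidine chloride. The median log2 fold change of all tested genes was 0.01. With scaling by library size alone that median was 0.12, and 57.9% of the changed genes were higher, against 47.7% with TMM scaling, so directions are given relative to the TMM scale. Changes of at least 2-fold were found for 2481 genes, of which 617 were higher and 1864 lower. The groups did not overlap for 9678 genes, 60.7% against 10% expected by chance.

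Of the 8 named genes with the lowest fold changes, at a mean FPKM of at least 5, all but TOMM6 had long genomic spans. FAF1, a ubiquitin-binding adaptor (523.2 kb), fell from 97.7 ± 2.15 to 4.87 ± 0.92 CPM, a log2 fold change of -4.32 ± 0.13. UTRN, which encodes utrophin (567.3 kb), fell with -4.18 ± 0.09, PRKCA, encoding protein kinase C alpha (508.1 kb), with -4.03 ± 0.15, and DACH1, a transcriptional cofactor (429.2 kb), with -3.93 ± 0.10. DIAPH3, a formin (498.4 kb), fell with -3.81 ± 0.12, DOCK1, a guanine nucleotide exchange factor (547.1 kb), with -3.80 ± 0.10 and ROBO1, the Slit receptor (1171 kb), with -3.69 ± 0.12. Genes of similar span to these 7 had medians between -3.12 and -2.81. TOMM6 (2.24 kb) was listed at -4.52 ± 0.63, but it overlaps AL365205.1. Its counts were 1330, 1342 and 388 in DMSO and 30, 82 and 36 after nitidine chloride, so its level is uncertain.

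The 8 named genes with the highest fold changes had genomic spans between 3.558 and 46.45 kb. NUPR1, a stress-induced chromatin protein, rose from 9.28 ± 0.71 to 49.9 ± 1.78 CPM, a log2 fold change of 2.42 ± 0.09. SLFN5, a Schlafen family member, rose with 2.35 ± 0.11, RAB39B, a small GTPase, with 2.14 ± 0.17 and CTSO, a cysteine cathepsin, with 2.13 ± 0.14. CHAC1, the glutathione-degrading enzyme, rose with 1.95 ± 0.38 and ZNF239, a zinc finger gene, with 1.91 ± 0.26. P2RY11 was listed at 2.38 ± 0.36 but overlaps PPAN and the readthrough gene PPAN-P2RY11, so its count is uncertain. The readthrough gene ATP5MF-PTCD1 had 0, 1 and 0 counts in DMSO and 381, 19 and 682 after nitidine chloride, overlaps ATP5MF and PTCD1, and did not pass with limma-voom, where its adjusted p was 0.196.

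Fold change differed between classes of genomic span, and above 20 kb the medians fell from class to class. Of the 1047 tested genes spanning 200 kb or more, 89.3% fell and 1.24% rose, with a median log2 fold change of -2.00. Between 100 and 200 kb, 75% of 1738 genes fell and 2.65% rose, with a median of -0.84. Between 50 and 100 kb the median was -0.21 and between 20 and 50 kb it was 0.14. Between 10 and 20 kb, 6.30% of 2396 genes fell and 44.2% rose, with a median of 0.30, close to the 6.69% and 44% of 1644 genes between 5 and 10 kb, with a median of 0.31. Below 5 kb, 12.3% of 2718 genes fell and 23.4% rose, with a median of 0.09. In each nitidine chloride library set against the mean of the DMSO libraries, the median of the genes of 200 kb or more was between -1.97 and -1.95, while single DMSO libraries against the other DMSO libraries gave -0.03 to 0.04.

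**Figure D2:**
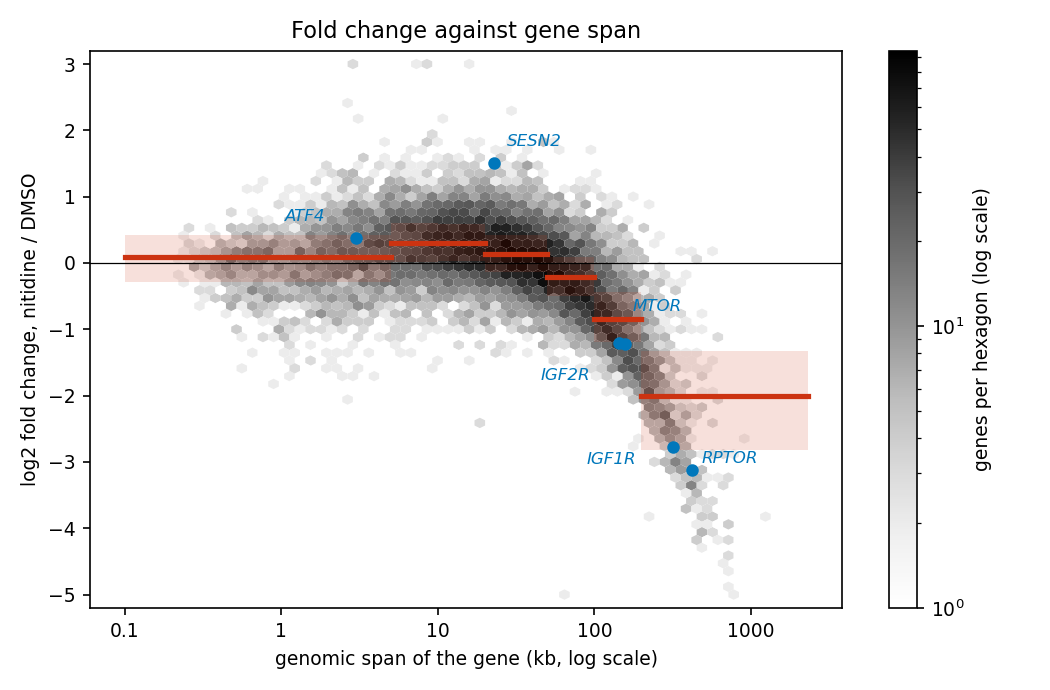
Log2 fold change of nitidine chloride over DMSO (vertical axis) against genomic span in kb (horizontal log axis) for 15953 genes, as hexagons shaded by the number of genes on a log scale, with fold changes beyond -5 and 3 drawn at those limits. Red lines are the medians of 7 span classes and pink bands the quartiles, and the medians go from 0.30 for genes of 10 to 20 kb to -2.00 for genes of 200 kb or more.

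Targets of ATF4 in the integrated stress response rose together. Of 46 tested members, 37 rose, 3 fell and 6 did not pass (37 higher and 4 lower when adjusted over the list alone), with a median log2 fold change of 0.64. NUPR1 and CHAC1 had the highest values. EPRS1, a tRNA synthetase, fell with -0.51 ± 0.06, and SLC7A11, the cystine transporter, fell with -0.40 ± 0.12. For SLC7A11 the adjusted p in edgeR's quasi-likelihood test was 0.0764 without DMSO replicate 2. It was 0.0843 with scaling by library size alone and 0.0526 with a replicate block. The camera test gave an adjusted p of 2.03e-12 (adjusted p = 0.238 with an estimated correlation).

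Components of mTORC1 and of nutrient sensing went both ways, with 7 of 30 higher, 10 lower and 13 not passing (9 higher and 10 lower when adjusted over the list alone). FLCN, the folliculin GTPase-activating protein, rose with 0.76 ± 0.09 and MIOS, a subunit of GATOR2, rose with 0.67 ± 0.08. RPTOR, the scaffold of mTORC1 (421.6 kb), fell with -3.12 ± 0.09 and FNIP2, a folliculin partner (138.9 kb), fell with -1.56 ± 0.08, where genes of similar span had medians of -2.80 and -0.86. The list as a whole did not pass (camera adjusted p = 0.704), and with scaling by library size alone 12 members were higher and 7 lower. Among inhibitors of mTORC1, 10 of 24 rose, 7 fell and 7 did not pass (11 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.548). SESN2 led those that rose, followed by C12orf66, a KICSTOR subunit, with 0.77 ± 0.11. GRB10, an adaptor that binds insulin receptors (203.4 kb), fell with -1.41 ± 0.08, and BMT2, an S-adenosylmethionine sensor (120.8 kb), fell with -1.18 ± 0.10. Genes of similar span to GRB10 and BMT2 had medians of -1.40 and -0.74, so the fall of GRB10 was that of its span class.

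Genes of the insulin and IGF axis fell as a group. Of 25 tested members, 17 fell, 3 rose and 5 did not pass (17 lower and 4 higher when adjusted over the list alone), with a median of -0.59. IGF1R, the IGF1 receptor (315.6 kb), fell with -2.78 ± 0.07, where genes of similar span had a median of -2.26. IGFBP4, an IGF-binding protein, rose with 1.53 ± 0.10. IGF2 rose with 0.42 ± 0.11, with an adjusted p of 0.0162 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which reached 0.0619 without DMSO replicate 2 and 0.0623 without DMSO replicate 3. The camera test gave an adjusted p of 6.63e-05 (adjusted p = 0.208 with an estimated correlation).

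Autophagy genes did not move together, with 12 of 49 higher, 16 lower and 21 not passing (13 higher and 17 lower when adjusted over the list alone; camera adjusted p = 0.574), and with scaling by library size alone 15 were higher and 14 lower. OPTN, an autophagy receptor, rose with 0.70 ± 0.11. ATG7, the E1-like enzyme of the pathway (285.4 kb), fell with -2.48 ± 0.10 and UVRAG (328.0 kb) fell with -2.54 ± 0.12. GABARAPL1, an ATG8 family member, had 1.68 ± 0.49, but its counts after nitidine chloride were 163, 720 and 662. Its adjusted p in edgeR's quasi-likelihood test was between 1.82e-04 and 0.0756 when single libraries were left out. With a replicate block it was 0.0593, and with limma-voom 0.0802. Lysosomal genes of the CLEAR network had 18 of 46 higher, 8 lower and 20 not passing (19 higher and 10 lower when adjusted over the list alone; camera adjusted p = 0.362). CTSL, cathepsin L, rose with 0.89 ± 0.16, and MITF, a transcription factor of the network (228.9 kb), fell with -1.78 ± 0.43.

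**Figure D3:**
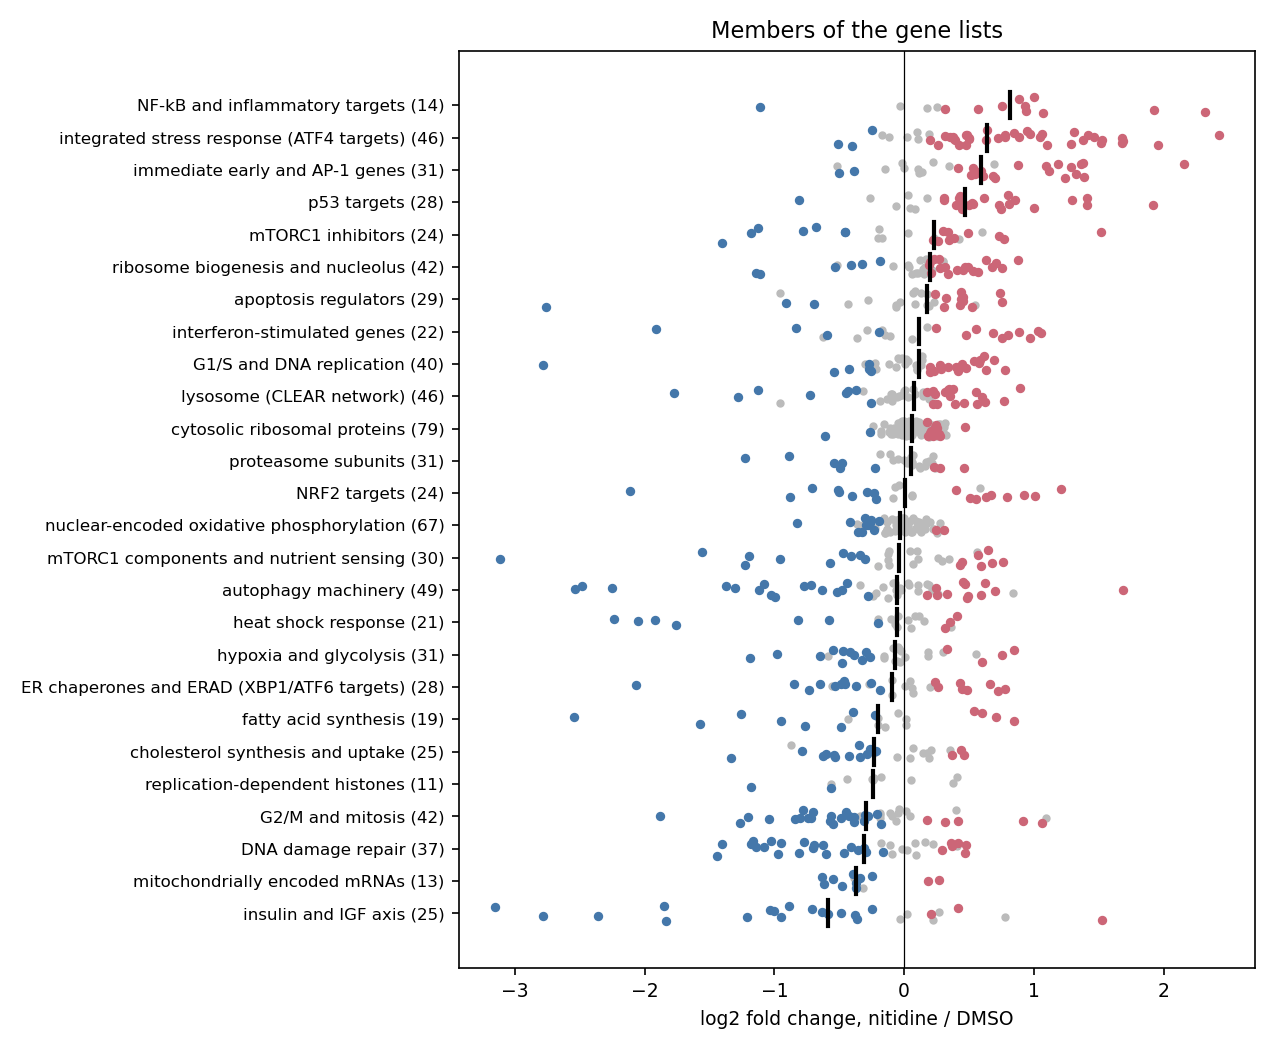
Log2 fold change of nitidine chloride over DMSO for the tested members of the 26 lists with at least 11 tested members, the number tested in parentheses. Red and blue points rose and fell past the adjusted p threshold, grey points did not pass, black bars are list medians, and the medians run from -0.59 for the insulin and IGF axis to 0.82 for NF-kB and inflammatory targets.

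Targets of p53 rose, with 21 of 28 higher, 1 lower and 6 not passing, both over all genes and adjusted over the list alone. PHLDA3, an AKT repressor, rose with 1.92 ± 0.13 and PLK2, a polo-like kinase, with 1.41 ± 0.13, while FBXW7, a ubiquitin ligase subunit (214.8 kb), fell with -0.81 ± 0.11. Genes of similar span to FBXW7 had a lower median, -1.465. The camera adjusted p was 2.14e-04 (adjusted p = 0.238 with an estimated correlation). Activity of p53 was not measured, so whether p53 drives the rise of this list is open. Of immediate early and AP-1 genes, 19 of 31 rose, 2 fell and 10 did not pass, again with equal numbers adjusted over the list alone. CCN2, a matricellular gene, rose with 2.16 ± 0.21 and FOSL2, an AP-1 subunit, with 1.38 ± 0.09, whereas DUSP1, a MAP kinase phosphatase, fell with -0.39 ± 0.08 and KLF10 fell with -0.50 ± 0.08. The camera adjusted p was 1.34e-03 (adjusted p = 0.699 with an estimated correlation).

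Targets of NF-kB had 10 of 14 tested members higher, 1 lower and 3 not passing, with the numbers equal when adjusted over the list alone. LIF, a cytokine, rose with 2.31 ± 0.40 from only 0.55 ± 0.33 CPM, and RELB, an NF-kB subunit, rose with 1.93 ± 0.21, while NFKB1 (116.0 kb) fell with -1.11 ± 0.10. The camera adjusted p was 0.0266 (adjusted p = 0.292 with an estimated correlation). DNA damage repair genes had 21 of 37 lower, 6 higher and 10 not passing, with equal numbers adjusted over the list alone. WRN, a RecQ helicase (140.0 kb), fell with -1.44 ± 0.13 and PRKDC, the DNA-dependent protein kinase (187.1 kb), with -1.40 ± 0.05, and PALB2, a BRCA2 partner, rose with 0.48 ± 0.13. Their camera adjusted p was 0.036 (adjusted p = 0.699 with an estimated correlation), and it was 0.0539 without DMSO replicate 3. Adjusted for genomic span, in a test added after the data had been seen, the list did not pass (adjusted p = 0.242), and its median of -0.31 lay at percentile 31.7 of random lists matched on span and expression.

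Lists that did not pass camera also held changed genes, to be read against the 51.7% of all tested genes that changed. Of G2/M and mitosis genes, 23 of 42 fell, 5 rose and 14 did not pass (23 lower and 6 higher when adjusted over the list alone; camera adjusted p = 0.117, and 0.0285 without nitidine chloride replicate 2), and the list passed downward in the span-adjusted test (adjusted p = 3.07e-08, and adjusted p = 0.169 with an estimated correlation). On the same z-scores without span adjustment, the G2/M list already had an adjusted p of 0.00878 in that test. CENPE, a kinetochore kinesin, fell with -1.88 ± 0.21, and HJURP, the CENP-A chaperone, rose with 1.06 ± 0.20. Of G1/S and replication genes, 17 of 40 rose, 6 fell and 17 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.243). E2F2 rose with 0.78 ± 0.08, and POLA1, the catalytic subunit of polymerase alpha (303.1 kb), fell with -2.78 ± 0.06. Of cholesterol genes, 12 of 25 fell, 3 rose and 10 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.574). With scaling by library size alone 8 were higher and 9 lower. The cholesterol list also passed downward in the span-adjusted test (adjusted p = 1.83e-05, and adjusted p = 0.169 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell with -1.33 ± 0.11. Of fatty acid genes, 8 of 19 fell, 4 rose and 7 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.125), among them ACACA, acetyl-CoA carboxylase (321.8 kb), with -2.54 ± 0.06.

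Heat shock genes had 7 of 21 lower, 3 higher and 11 not passing, with equal numbers adjusted over the list alone (camera adjusted p = 0.261), and with scaling by library size alone 7 were higher and 6 lower. Span-adjusted, the list passed downward (adjusted p = 2.46e-04, and adjusted p = 0.281 with an estimated correlation). HSPA1B, an inducible HSP70 gene, fell from 713.6 ± 48.0 to 172.1 ± 12.9 CPM. It is near-identical to HSPA1A, which was listed at 6.88 ± 0.47 CPM in DMSO and 1.46 ± 0.34 CPM after nitidine chloride. The split of reads between both is uncertain, but both entries fell. Of genes for ER chaperones and ER-associated degradation, 8 of 28 rose, 11 fell and 9 did not pass (8 higher and 12 lower when adjusted over the list alone; camera adjusted p = 0.706), and with scaling by library size alone 10 were higher and 9 lower. HERPUD1 rose with 0.77 ± 0.11, and ATF6, an ER stress sensor (197.8 kb), fell with -2.07 ± 0.07. Of 13 mitochondrially encoded mRNAs, 9 fell, 2 rose and 2 did not pass (10 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.227, and span-adjusted, downward, 4.46e-04 or, with an estimated correlation, adjusted p = 0.404), with -0.62 ± 0.05 for MT-ND5 and 0.27 ± 0.05 for MT-ND1.

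Of cytosolic ribosomal protein genes, 11 of 79 rose, 2 fell and 66 did not pass (0 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.205, and 0.0204 without nitidine chloride replicate 3). With scaling by library size alone 27 were higher and 1 lower. RPL3 fell with -0.61 ± 0.13. Of ribosome biogenesis genes, 19 of 42 rose, 6 fell and 17 did not pass (20 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.0918, and 0.0285 without nitidine chloride replicate 2). Scaled by library size alone, 29 ribosome biogenesis genes were higher and 5 lower. POLR1C rose with 0.75 ± 0.07 and UTP20 (106.5 kb) fell with -1.14 ± 0.07. Nuclear-encoded oxidative phosphorylation genes had 2 of 67 higher, 11 lower and 54 not passing (1 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.706), and the list's median was -0.03 although camera ranked it upward and the span-adjusted test called it downward (adjusted p = 1.88e-04, and adjusted p = 0.548 with an estimated correlation), and with scaling by library size alone 12 members were higher and 5 lower. Proteasome genes had 3 of 31 higher, 6 lower and 22 not passing (2 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.885), with a median of 0.05 and a mean of -0.05, and with scaling by library size alone 10 were higher and 5 lower. Of 48 replication-dependent histone genes, only 11 reached the count minimum, so most of the list was not tested. Of the tested members 0 were higher, 2 were lower and 9 did not pass (0 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.957).

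Of targets of NRF2, 9 of 24 rose, 9 fell and 6 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.653), with NQO1 at 1.21 ± 0.14 and ME1 (220.7 kb) at -2.11 ± 0.09. Of hypoxia and glycolysis genes, 4 of 31 rose, 11 fell and 16 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.706, and span-adjusted, downward, 0.0449 or, with an estimated correlation, adjusted p = 0.552), with VEGFA at 0.85 ± 0.11 and PDK1 at -1.19 ± 0.07. Of interferon-stimulated genes, 10 of 22 rose, 4 fell and 8 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.394), with IRF1 at 1.03 ± 0.11, IFIT1 at -0.83 ± 0.06 and DDX58, which encodes the RNA sensor RIG-I, at -1.91 ± 0.13. DDX58 went from 49.4 ± 6.83 to 13.1 ± 1.44 CPM, and genes of similar span had a median of -0.22. Of apoptosis regulators, 11 of 29 rose, 3 fell and 15 did not pass, with equal numbers adjusted over the list alone (camera adjusted p = 0.418), with HRK at 0.76 ± 0.08 and BCL2 (196.8 kb) at -0.91 ± 0.10. BCL2L2 had the lowest value of that list, -2.76 ± 0.09, where genes of similar span had a median of 0.32, but it overlaps the readthrough gene BCL2L2-PABPN1, so its count is uncertain. Genes of similar span to BCL2 had a median of -1.355, lower than BCL2 itself.

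Markers of other cell types were mostly below the count minimum. Of leukocyte markers 5 of 20 were tested, with 2 higher and 3 not passing (camera adjusted p = 0.258), of fibroblast markers 8 of 14, with 3 higher and 5 not passing (camera adjusted p = 0.283), of keratinocyte markers 5 of 14, with 2 higher and 3 not passing (camera adjusted p = 0.394), and of renal tubule markers 5 of 15, with 1 higher, 1 lower and 3 not passing (camera adjusted p = 0.885). Adjusted over the list alone the numbers were equal, except for 2 lower renal tubule markers. CORO1A rose from 9.85 ± 0.96 to 20.4 ± 1.72 CPM and COL1A1 from 32.6 ± 2.29 to 52.7 ± 3.73 CPM. Of the 30 lists, 6 passed camera with the preset correlation and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05.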

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

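The span-adjusted list tests and the count without overlapping genes were chosen after the result was seen. Against 8250 changed genes in the main test, DESeq2 called 7751, limma-voom 8242 and edgeR 8266 without a filter on low counts, 7525 with a mean count of at least 50 and 7057 to 7828 when single libraries were left out, and no gene called in both changed sign in any of these fits. With the replicate number as a block 7555 genes changed, 7378 of them among the 8250. Same-numbered libraries did not deviate together (correlations -0.096 to 0.038), so the numbers were not read as pairs. At an adjusted p of 0.01, 2616 genes were higher. Without overlapping genes, which left 7161 genes tested, 3810 changed, 1924 higher and 1886 lower, 1059 of them at least 2-fold. A test against a 1.5-fold change called 2833 genes. The correlation of fold change with genomic span was -0.161 without a count filter and -0.581 with a mean count of at least 50. Among the tested genes it was -0.263 in those of lowest expression, -0.633 in the middle class and -0.597 in the highest of 3 equal classes, so it was weaker where counts were low. With an estimated correlation the adjusted p was 0.208 for the insulin and IGF axis and 0.238 for ATF4 targets, and when also span-adjusted 0.281 and 0.242. Fry, which does not compare with other genes, passed 21 of the 30 lists. Among them were autophagy (2.09e-04) and mTORC1 components (0.00652), both downward. Some lists past no threshold in the main test turned direction, and the cause was not tested. These were proteasome genes without a count filter (0.979), in fry (0.265), span-adjusted (0.0892, or 0.649 with an estimated correlation) and without nitidine chloride replicate 2, with 0.681 to 0.949 over all 6 fits that leave out 1 library; renal tubule markers without a filter (0.979), in limma-voom (0.960) and span-adjusted (0.0607, or 0.326 with an estimated correlation); histones in DESeq2 (0.908) and without DMSO replicate 1, with 0.839 to 0.998 over those 6 fits; oxidative phosphorylation genes in limma-voom (0.756), in fry (0.480), span-adjusted (1.88e-04, or 0.548 with an estimated correlation) and without nitidine chloride replicate 2, with 0.403 to 0.904 over those 6 fits; NRF2 targets in fry (0.937); and, span-adjusted, autophagy genes (0.907, or 0.911 with an estimated correlation), ribosomal proteins (0.158, or 0.803) and interferon-stimulated genes (0.458, or 0.552). Scaling by library size alone turned the sign of the list medians of ER chaperones (-0.09 to 0.01), mTORC1 components (-0.04 to 0.07), autophagy (-0.05 to 0.05), oxidative phosphorylation (-0.03 to 0.08), heat shock (-0.05 to 0.05) and hypoxia genes (-0.07 to 0.04), none of which passed camera. Of the values for named genes, 1443 kept direction and side of the threshold, 52 lost the call and 0 reversed. Of the list tests 402 kept both, 31 newly passed, 18 no longer passed and 23 reversed. The simulation changed few genes, whereas 51.7% of the tested genes changed here, so its adjusted threshold was stricter. Its call rate of 33.3% at 1.5-fold is not the sensitivity of this comparison, which was not measured.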

Other observations

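The gene families in this part, and the comparisons of lists and single genes with others of similar span, were tests chosen after the result was seen. 13 families were tested. Genes around P-TEFb, the kinase that releases paused RNA polymerase II, went both ways, with 5 of 15 higher, 5 lower and 5 not passing (camera adjusted p = 0.538). HEXIM1, the P-TEFb inhibitor, rose from 89.9 ± 2.70 to 273.8 ± 14.4 CPM (n = 3), a log2 fold change of 1.61 ± 0.06. MEPCE, which caps 7SK RNA, rose with 1.07 ± 0.06, HEXIM2 with 0.99 ± 0.14, CCNT1 with 0.62 ± 0.06 and CDK9, the kinase itself, with 0.46 ± 0.09. Zinc finger genes with ZNF symbols had 154 of 429 higher, 41 lower and 234 not passing (camera adjusted p = 0.00322, adjusted p = 0.266 with an estimated correlation). Host genes of small nucleolar RNAs had 13 of 23 higher and 0 lower (camera adjusted p = 0.0219, adjusted p = 0.266 with an estimated correlation), such as SNHG12 with 0.93 ± 0.11. Tubulins had 8 of 14 higher and 0 lower (camera adjusted p = 0.0219, adjusted p = 0.571 with an estimated correlation), with TUBB3 at 1.42 ± 0.18. Adjusted for genomic span, none of these 3 families passed, with an adjusted p of 0.152 for zinc finger genes, 0.159 for the host genes and 0.152 for tubulins.

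Heterogeneous nuclear ribonucleoproteins, which package and splice pre-mRNA, had 11 of 20 lower, 2 higher and 7 not passing although their median span was 14.1 kb. HNRNPA3 fell with -1.30 ± 0.08 and HNRNPD with -1.05 ± 0.06. The camera call depends on how the family was drawn: the first symbol pattern took 24 genes, among them antisense and readthrough ones, and gave a camera adjusted p of 0.0272, and the narrower pattern of 20 genes, set after that value was seen, gave 0.0715 (adjusted p = 0.266 with an estimated correlation in both). Adjusted for genomic span, the family passed downward with both patterns, with an adjusted p of 3.79e-11 and 8.45e-09 (adjusted p = 0.043 and 0.0328 with an estimated correlation). Collagens had 15 of 28 lower and 6 higher, with a camera adjusted p of 0.040 beside the first patterns and 0.050 beside the narrower ones, and a median span of 152 kb. Their adjusted p was 0.266 with an estimated correlation, and adjusted for span the direction turned upward without passing (0.152). The other 7 families did not pass in either version: SR splicing factors (0.538), solute carriers (0.292), kinesins (0.133), cytosolic (0.475) and mitochondrial (0.138) tRNA synthetases, mitochondrial ribosomal proteins (0.0715) and RNA polymerase II subunits (0.133), as camera adjusted p with the narrower patterns. Scaling by library size alone turned the sign of 1 family median, that of SR splicing factors, from -0.01 to 0.09.

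Longer genes were lower after nitidine chloride, with a Spearman correlation across genes of -0.474 between fitted log2 fold change and genomic span, where genes are not independent replicates. The correlation was -0.473 to -0.441 in single nitidine chloride libraries and -0.117 to 0.114 in single DMSO libraries set against the others. The correlation was -0.451 given FPKM length, which is not a mature transcript length, so an effect of the latter was not settled. RNA degradation was not tested. Given GC content and FPKM length the correlation was -0.408, which argues against GC content. That the treatment lowers transcripts of long transcription units restates this pattern and stays a hypothesis, since transcription itself was not measured.

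Adjusted for genomic span, 11 of the 30 lists passed with the preset correlation, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.169. Those higher were ATF4 targets (adjusted p = 3.16e-10), p53 targets (1.88e-04), immediate early genes (0.0449) and NF-kB targets (0.0449). Those lower were G2/M (3.07e-08), cholesterol (1.83e-05), oxidative phosphorylation (1.88e-04), heat shock (2.46e-04), mitochondrially encoded (4.46e-04), insulin and IGF (0.0449) and hypoxia genes (0.0449). On the same z-scores without span adjustment, this test already gave an adjusted p of 0.00878 for G2/M, 0.0147 for mitochondrially encoded and 0.00453 for insulin and IGF genes. It gave 0.252 for cholesterol, 0.801 for oxidative phosphorylation, 0.345 for heat shock and 0.314 for hypoxia genes. Each of the higher lists also passed without span adjustment. Among 10000 random lists matched on span and expression, the medians of the G2/M, cholesterol and oxidative phosphorylation lists lay at percentile 0. Cytosolic ribosomal proteins lay at 0.03, mitochondrially encoded mRNAs at 0.05, heat shock at 0.71 and hypoxia at 18.1. Immediate early genes and NF-kB targets lay at 100, p53 targets at 99.8 and mTORC1 inhibitors at 99.7. The span-adjusted test did not call the ribosomal proteins (0.158) or the mTORC1 inhibitors (0.102).

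ATF4 targets were higher than their spans would give. Their median of 0.64 lay at percentile 100 of 10000 random lists matched on span and expression, so span alone is unlikely as the explanation. The matched lists carry no correlation between genes, and the span-adjusted test gave an adjusted p of 0.242 with an estimated correlation. An effect of the treatment on ATF4 activity stays open and was not tested.

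The lower insulin and IGF axis may in part follow from long genes. Its median of -0.59 lay at percentile 0.59 of 10000 matched lists, whose median was -0.19, so span alone gives less than the shift seen, although the span-adjusted test gave an adjusted p of 0.281 with an estimated correlation. For the single genes the reading is different: 26.1% of genes of similar span were lower than IGF2R and 32.3% were lower than MTOR, so genomic span could account for both falls in mRNA. The rise of ATF4 likewise lay within the range of genes of similar span, 65.2% of which were lower, while 98.7% were lower than SESN2. IGF2R protein was not analysed here.

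The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 8250 changed genes in edgeR's quasi-likelihood test and the highest other split gave 1. Every other split mixes DMSO and nitidine chloride libraries within its groups, so a difference between treatments widens their spread and lowers the calls. No conclusion on chance is drawn from this contrast.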
